A study of Rattus norvegicus with 10 samples.

How the data were processed

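Total RNA from whole mammary glands of female rats at postnatal day 21, around weaning, was converted to biotin-labelled cRNA and hybridised to 1-colour oligonucleotide arrays, 1 array per sample, per the labels. Exposure to a diet based on casein or on soy protein isolate began at gestation day 4, per the labels, which give 5 arrays for each diet. The labels speak of RNA pools and of replicate cRNA targets made from each pool. It is therefore not clear that every array is a separate animal, and the p-values measure the spread between these samples, which may be partly technical. The labels name no litter, hybridisation batch or scan date, and the replicate numbers of the diets do not overlap, so no pairing was used. The number of arrays limits the precision, and the median standard error of a soy minus casein difference was 0.144 on the log2 scale.

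The values are the intensity (signal) of each probe set on a linear scale, made by the authors with MAS5, per the submitters' processing notes. The version of MAS5 and its settings are not given in the sources used here. In the deposited table the 2% trimmed mean of the signal was 500.1 on every array, with a spread of 0.0048%, so the deposited scaling was kept. The median signal per array ranged from 255.7 to 286. Detection calls were not used here, so a dim probe set could not be set against background, and a filter on the mean signal took that place.

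From these values, signals below 1 were set to 1 and log2 was taken. The table held 15923 probe sets, of which 57 controls were left out of the tests. Of the other 15866, the annotation named 1 gene for 12783, several genes for 312 and none for 2771. Probe sets with several genes were given no name. Gene identifiers of 12748 probe sets were found in the reference gene table (assembly GRCr8), which changed 0 symbols, and none of its coordinates were used. A probe set was tested when its mean log2 signal over the 10 arrays was at or above the 40th percentile, 7.47, which is a signal of 177. This left 9520 probe sets, 1371 of them unnamed, for 7151 genes.

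Probe sets were compared between the diets with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided), with Benjamini-Hochberg adjustment over all probe sets tested and a threshold of 0.05. Fold changes are soy minus casein on the log2 scale. For gene lists the probe set with the highest mean signal stood for each gene, and the shift of a list was tested with camera in limma with an inter-gene correlation of 0.01, adjusted over the 28 lists with at least 5 tested members. The 31 lists cover epithelial, adipose, immune, vascular, nerve, muscle, skin and blood markers, metabolism, hormone response, proliferation, signalling, matrix, stress and clock genes, and 1 list is not reported here. The lists share few members, at most 3 between any pair. Members were also counted as adjusted over the list alone. An exact permutation test over the 252 assignments of the arrays, whose smallest two-sided p is 0.0079, was used for the RNA quality ratios and for list means per array.

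The genes named are, by rule, those that passed the threshold, filled up to 20 with the single-gene probe sets of smallest p, then the tested members of each list with the smallest p, up to 4, and 23 genes chosen for the tissue. After the values were seen, the members named were narrowed to 4 for lists that passed and 2 for other lists. The design, the lists, the rule and most alternatives were fixed before the data were examined.

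The steps were tested on simulated data drawn from the means and spread of the 9520 probe sets in a soy against casein comparison of the same size, with 200 probe sets changed. The test recovered 44% of the 1.5-fold changes, 80% of the 2-fold, 96% of the 4-fold and 96% of the 8-fold changes. There were 50 changes of each size and 6 false calls. The simulated noise was independent between probe sets, without the signal that genes share within an array. These shares therefore do not give the recovery or error rate in the real arrays. The alternatives tried were quantile normalization, median centring, no filter and a filter at the 60th percentile, log2 of the signal plus 16, other variance models, array weights, the actin 3' to 5' ratio as a covariate, leaving out each array, probe-wise statistics without moderation, a rule of unadjusted p and 1.5-fold, other set tests and the mean of a gene's probe sets. Leaving out arrays with muscle or without lymph node signal, using these signals as covariates and the exact permutation of list means were added after seeing the data.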

Results

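Gene expression was measured with MAS5 signals from 1-colour arrays in whole mammary glands of female SD rats at postnatal day 21. The rats had been exposed from gestation day 4 until weaning to an AIN-93G diet, a purified rodent diet, whose protein was casein or soy protein isolate. There were 5 arrays for each diet, and 9520 probe sets for 7151 genes were tested. Any pair of arrays correlated with a Spearman coefficient of 0.925 to 0.983 within a diet (median 0.954) and of 0.924 to 0.981 between diets (median 0.957).

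The comparison asks how dietary soy protein affected the early mammary gland. Transcripts for making fatty acids and triglycerides, and to a smaller extent cholesterol, were lower as groups in soy-fed glands, and muscle and nerve transcripts were higher as groups, while no single gene passed the test. All 4 group calls came from camera with a preset correlation. Each had an adjusted p of 0.97 in camera with an estimated correlation, and of 0.96 in the exact permutation test. All 28 lists share these adjusted values, which therefore do not rank them. The unadjusted p in camera with an estimated correlation was 0.095 for fatty acid and triglyceride synthesis and 0.20 for cholesterol synthesis. It was 0.30 for skeletal muscle and 0.055 for nerve and Schwann cells. Of 100 splits of the arrays into groups of 5, the diets included, 86 called at least 4 lists and 50 called the synthesis list. Such calls thus also arise without regard to diet. The muscle signal was highest in 4 arrays, 1 of casein and 3 of soy. Leaving out 1 array moved 41 of 94 gene values and 27 of 28 list means by over 1.5 times or turned their sign. The exception among the lists was fatty acid and triglyceride synthesis, with a mean of -0.38 that was -0.26 without casein 18. A list mean that is small to begin with crosses this limit easily, so the count does not rank the lists by stability. Among probe sets that name 1 gene, the smallest p was that of Hsd11b1, the enzyme that regenerates active glucocorticoid, with a log2 fold change of 0.81 ± 0.19 (SE, n = 5 per diet). Pnpla3, a lipid droplet enzyme of triglyceride metabolism, had a log2 fold change of -1.25 ± 0.29 (SE). In limma, 0 probe sets had an adjusted p under 0.05, the smallest adjusted p was 0.98 and the smallest unadjusted p was 0.000502. There were 433 probe sets with an unadjusted p under 0.05, 220 higher and 213 lower in soy. Of these, 45 also had at least a 1.5-fold difference (16 higher, 29 lower). By chance 476, or 5% of those tested, would have such a p. The other splits of the arrays had a median of 378, and those that part casein 6 and soy 149, as the diets do, of 251. Of the 100 splits, 45 reached 433. Of the 52 other splits that part casein 6 and soy 149, 6 did. Statistics without moderation also called 0 probe sets at an adjusted p under 0.05. The samples of the diets did not overlap for 76 probe sets, where chance gives 76.

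The other genes with the smallest p, each with an adjusted p of 0.98 in limma, belonged to several functions. Among genes of lipid handling, the log2 fold changes were 0.52 for Pla2g15, a lysosomal phospholipase, -0.67 for Lyplal1, a lysophospholipase-like protein, -0.48 for Cpt2, the inner mitochondrial carnitine palmitoyltransferase, and -0.60 for Fads1, the delta-5 fatty acid desaturase. Among genes of growth control and signalling they were 0.90 for Cish, an inhibitor of cytokine signalling induced by STAT5, 0.39 for Cdkn1b, the cell cycle inhibitor p27, and 0.56 for Pmepa1, an inhibitor of TGF-beta signalling. For Gabarapl1, an autophagy protein, the value was 0.53, for the quinone reductase Nqo2 -0.40, for the phenylalanyl-tRNA synthetase subunit Farsb -0.39 and for Lrrc8d, a volume-regulated anion channel subunit, -0.60. Values were 0.53 for Fam107a, 0.77 for Yju2b, -0.59 for Adam23, -0.43 for Lrrc41 and 0.36 for Med16. Probe sets disagreed in sign for 2 genes, Aarsd1, with 0.46 and -0.11, and Hnrnpu, with -0.65, -0.14 and 0.07.

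The genes of fatty acid and triglyceride synthesis were lower in soy as a group. Of 23 tested members, 18 had a negative and 5 a positive log2 fold change, with a mean of -0.38 and a median of -0.45 (camera in limma, adjusted p = 5e-07; adjusted p = 0.97 with an estimated correlation). No member passed over all probe sets, and 2, Pnpla3 and Fads1, passed when adjusted over the list alone. Me1, malic enzyme, which supplies NADPH, had a log2 fold change of -0.99 ± 0.30 (SE), and Fasn, fatty acid synthase, of -0.63 ± 0.23 (SE) at its brightest probe set and of -1.23 at another. Scd, a stearoyl-CoA desaturase, was at -0.45 ± 0.21 (SE), and at -0.29 without soy 147. The mean of the list per array was 10.91 ± 0.31 (SD, n = 5) in casein and 10.53 ± 0.24 (SD, n = 5) in soy. An exact permutation test of these means gave p = 0.063. All 5 soy arrays lay below the casein mean, but so did casein 10, casein 6 and casein 7, at 10.81, 10.69 and 10.61. Soy 149, at 10.84, lay above these casein arrays. Casein 18 was highest, at 11.38, and without it the shift was -0.26. With the muscle and lymph node signals of each array as covariates the shift was -0.22 (adjusted p = 0.071 in limma, against 8.8e-12 to 0.98 over all alternatives).

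**Figure D1:**
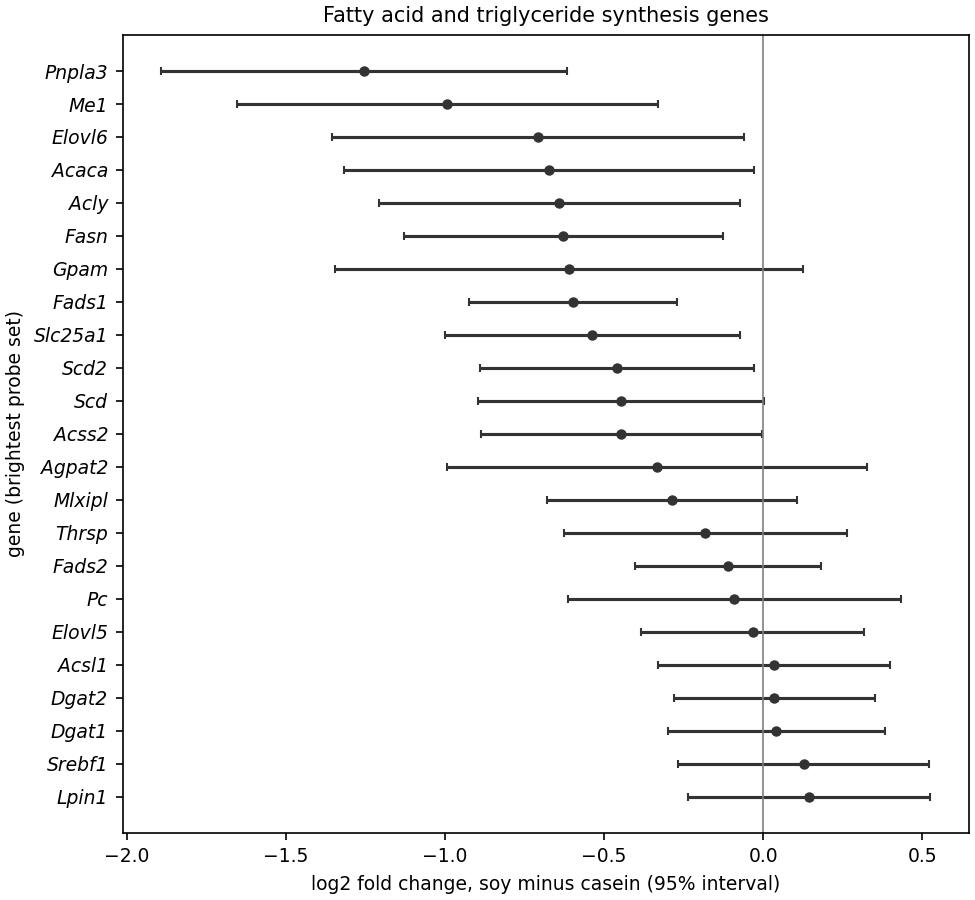
Log2 fold change, soy minus casein, of the 23 tested genes of fatty acid and triglyceride synthesis, 1 row per gene, with points for the estimate from limma and bars for its 95% interval. Of the 23 points, 18 lie below 0, the lowest at -1.25 for Pnpla3.

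Cholesterol synthesis genes were also lower in soy as a group. Of 16 tested members, 12 had a negative and 4 a positive log2 fold change, with a mean of -0.20 and a median of -0.21 (camera in limma, adjusted p = 0.0029; adjusted p = 0.97 with an estimated correlation), and 0 passed when adjusted over the list alone. The sterol reductase Dhcr7 had a log2 fold change of -0.45 ± 0.15 (SE), Nsdhl of -0.59 ± 0.26 (SE), the lanosterol demethylase Cyp51 of -0.44 ± 0.20 (SE) and Acat2, acetyl-CoA acetyltransferase, of -0.56 ± 0.25 (SE). The mean per array was 9.15 ± 0.31 (SD, n = 5) in casein and 8.95 ± 0.11 (SD, n = 5) in soy (exact permutation p = 0.22). All 5 soy arrays lay below the casein mean, but so did casein 10, casein 6 and casein 7, at 9.078, 8.766 and 9.039. Casein 6 was lower than every soy array, and casein 18 was highest, at 9.598. The call was lost without casein 18, at -0.086 (adjusted p = 0.22), where Cyp51 was at -0.26 and Acat2 at -0.34, and with muscle and lymph node signals as covariates, at -0.12 (adjusted p = 0.071; 7.7e-06 to 0.98 over all alternatives in limma). With the actin 3' to 5' ratio as a covariate it was -0.32.

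Skeletal muscle genes were higher in soy as a group, but the signal differed widely between arrays of the same diet. Of 19 tested members, 16 had a positive and 3 a negative log2 fold change, with a mean of 1.74 and a median of 2.19 (camera in limma, adjusted p = 0.0014; adjusted p = 0.97 with an estimated correlation). The list mean was 12.52 in casein 6, 12.41 in soy 157, 12.1 in soy 149 and 11.23 in soy 147, and between 6.995 and 8.205 in the other 6 arrays, so 3 of 5 soy arrays lay above the casein mean of 8.45 ± 2.32 (SD, n = 5). Among members, Myl11, a fast-muscle myosin light chain, had a log2 fold change of 4.25 ± 2.46 (SE), the calcium-binding Pvalb of 3.58 ± 2.31 (SE) and Myl1 of 2.41 ± 1.56 (SE). Myl11 lay between 12.96 and 14.39 in those 4 arrays, at 7.472 in casein 7 and 8.145 in soy 155, and between 3.154 and 3.42 in the other 4. Pvalb lay between 3.018 and 3.678 in these last 4, also far under the 7.47 of the filter. No signal was set against background there, so the sizes of both differences and of the list mean are not exact. Probe sets of Myh1, a fast myosin heavy chain, ran from -0.26 at the brightest to 0.30. Genes of nerve and Schwann cells were higher in 8 of 9 tested members, with a mean of 0.35 and a median of 0.22 (camera in limma, adjusted p = 0.0015; adjusted p = 0.97 with an estimated correlation). The myelin genes Mbp and Mal had log2 fold changes of 0.61 ± 0.29 (SE) and 0.71 ± 0.27 (SE), Cldn19 of 0.94 ± 0.36 (SE) and Cnp of 0.22 ± 0.13 (SE). The nerve list mean was highest in the 4 arrays with the highest muscle signal. It was 10.22 in soy 149, 9.73 in soy 157, 9.62 in soy 147 and 9.485 in casein 6, against 9.094 to 9.416 in the other 6. Without soy 149 Mbp was at 0.36 and Mal at 0.45, and without casein 6 Cnp was at 0.12. Exact permutation tests of the array means gave p = 0.38 for muscle and p = 0.071 for nerve. Without the 4 arrays with the highest muscle signal the nerve shift was 0.061 (adjusted p = 0.42), while the muscle shift of 0.034 (adjusted p = 0.85) follows from how these arrays were chosen and tests nothing. The filter was applied again to the arrays kept in each such setting. Over the muscle genes tested with all arrays the shift was 0.168. The muscle call was also lost without soy 149, at 1.24 (adjusted p = 0.14), or soy 157, at 1.16 (adjusted p = 0.13), and the shift was 2.715 without casein 6 (adjusted p = 2.4e-10) and 2.62 without soy 159 (adjusted p = 2.4e-09). The nerve call was lost without soy 149, at 0.15 (adjusted p = 0.15), without both casein 6 and soy 149, at 0.19 (adjusted p = 0.052), and with no filter, at 0.14 (adjusted p = 0.25). It was kept with the muscle and lymph node signals as covariates. With the actin 3' to 5' ratio as a covariate the muscle shift was 2.71 and the nerve shift 0.53. Over all alternatives in limma the adjusted p ran from 2.4e-10 to 0.98 for muscle and from 2.3e-06 to 0.98 for nerve.

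**Figure D2:**
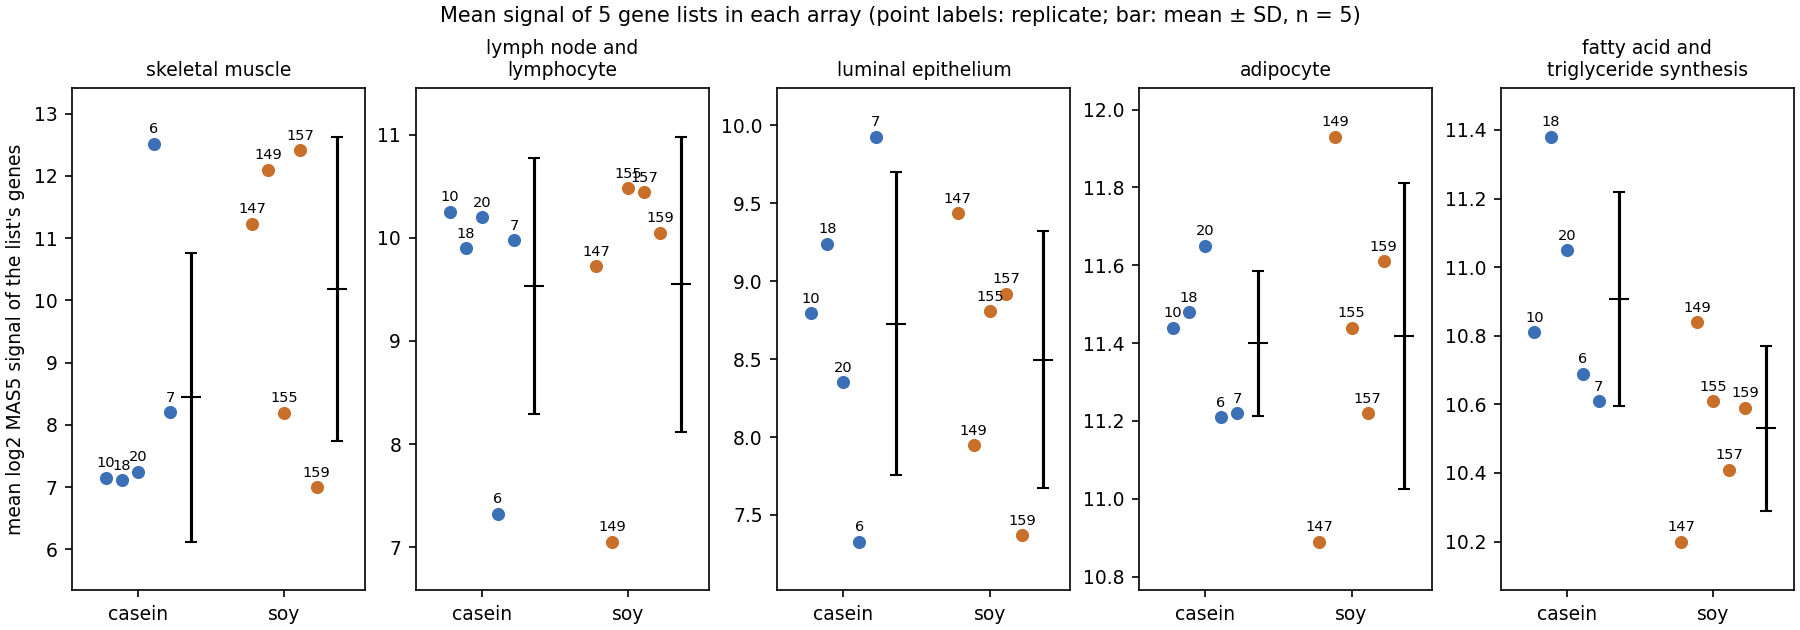
Mean log2 signal of 5 gene lists in each array, with points labelled by replicate number, coloured by diet, and bars for the mean ± SD of 5 arrays. The skeletal muscle mean was between 11.23 and 12.52 in 4 arrays, and the lymph node mean was 7.324 in casein 6 and 7.054 in soy 149.

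Other cell types showed no diet shift that passed. Lymph node and lymphocyte genes (18 tested, mean 0.02) were low in casein 6, at 7.324, and soy 149, at 7.054, against 9.721 to 10.48 in the other 8 arrays, and the list passed without soy 149, at 0.64 (camera in limma, adjusted p = 4.3e-04), and stood at -0.53 without casein 6 (adjusted p = 0.13). Means were 0.04 for antigen presentation and interferon genes (19 tested), which passed without soy 149 at 0.30 and stood at -0.18 without casein 6, 0.07 for macrophage and myeloid genes (18 tested), which passed without casein 10, soy 149 or soy 157 at 0.10 to 0.18, and 0.03 for mast cell genes (8 tested). In these lists Cd37 was at -0.40, but at 0.14 without soy 149, where its signal was 6.98, and Cxcr5 at 0.25, RT1-Bb at 1.35 and Tapbp at 0.28, Lgals3 at 0.34 and Cybb at 0.17, and Tpsb2 at 0.33 and Hdc at -0.22. Luminal epithelial genes (11 tested, 5 positive and 6 negative) had a mean of -0.23, which was -0.66 without casein 6 and turned to 0.068 without casein 7 and 0.046 without soy 159. Krt8 was at -0.75 ± 0.75 (SE), Krt18 at 0.08 ± 1.03 (SE) and Epcam at -1.17 ± 1.08 (SE). Without soy 159, where Epcam was at 4.53, the Epcam value was -0.18, and without 1 array the values ran from -1.85 to -0.18 for Epcam and from -1.28, without casein 6, to -0.28, without casein 7, for Krt8. Krt18 was at 4.492 in casein 6, against 8.992 to 10.93 in the other casein arrays, and its value without casein 6 was -0.98. Basal and myoepithelial genes (10 tested) had a mean of -0.04 (-0.43 without soy 147 and 0.21 without soy 159), with Egfr at -0.45 and Acta2 at -0.18, and genes of milk proteins and secretory differentiation (6 tested, 3 positive and 3 negative) of -0.07 (-0.55 without casein 6 and 0.18 without soy 159), with Plin2 at -0.12 and Xdh at 0.09. Without the 4 arrays with the highest muscle signal, which leaves 4 casein and 2 soy arrays, the luminal list passed at -1.15 and the basal list at -0.76. Of these 2 soy arrays, soy 159 had luminal and basal means of 7.37 and 8.126, below all 4 casein arrays. Soy 155, at 8.809 and 9.065, lay within their ranges of 8.351 to 9.926 and 8.97 to 9.94. Adipocyte genes (18 tested, 11 positive and 7 negative) had a mean of 0.02, with Pparg at 0.22, Cebpa at -0.49, Fabp4 at 0.18, Lep at -0.38 and Cfd at 0.25. The list passed without soy 147 at 0.15 and turned to -0.11 without soy 149. Lep was at -0.73 without soy 149 and -0.16 without soy 157, Cebpa at -0.26 without soy 147, and Pparg at 0.13 without casein 6 and 0.35 without soy 147. The sign turned under quantile normalization for Fabp4 and the adipocyte list, and under median centring for the adipocyte and lymph node lists. Endothelial genes (13 tested) had a mean of 0.06, with Kdr at -0.27 and Cldn5 at 0.29, extracellular matrix and fibroblast genes (35 tested) of -0.09, with Lum at -0.37 and Col12a1 at -0.42, and basement membrane genes (16 tested) of -0.08, with Col18a1 at -0.31 and Col4a5 at -0.48. The matrix list passed without casein 10, casein 20 or soy 149, at -0.14 to -0.11, and the basement membrane list without soy 149, at -0.16. Over all settings without 1 array the means ran from -0.14 to -0.042 for matrix and from -0.16 to -0.034 for basement membrane. Fewer than 5 members were tested of the brown adipocyte (3), skin (3) and blood (4) lists, where Cidea was at -0.29, Cpt1b at -0.16, Sprr1a at 1.56, Calml5 at 0.56, Hbb at 0.25 and Alas2 at 0.20. The skin values rested on soy 147, at 12.91 for Sprr1a and 10.24 for Calml5, and without it Calml5 was at 0.057 and Sprr1a lay below the filter.

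Hormone, growth and signalling lists did not pass. Genes of the growth hormone, prolactin and IGF axis (17 tested, 8 positive and 9 negative) had a mean of 0.006, and 1 member, Cish, passed when adjusted over the list alone. Igfbp3, an IGF binding protein, was at 0.70 ± 0.22 (SE), Igf1 at -0.21 and Prlr, the prolactin receptor, at -0.22 and 0.19 at 2 probe sets. The first of these was at 0.063 without casein 18 and -0.65 without casein 6. Estrogen response genes (11 tested) had a mean of 0.03, with Igfbp4 at -0.38 and Ctsd at 0.19. Cell cycle genes (24 tested, 6 positive and 18 negative) had a mean of -0.13 (camera in limma, adjusted p = 0.10), with Mki67 at -0.39, Mcm2 at -0.34, Aurkb at -0.31 and Ccnd1 at -0.08. Without soy 149, where its signal was 7.66, Mki67 was at -0.084, and Ccnd1 ran from -0.19 without soy 157 to -0.0052 without casein 7. That list passed at -0.22 to -0.14 when any of casein 10, casein 20, casein 6, soy 155 or soy 157 was left out, and stood at 0.0012 without soy 149 (adjusted p = 0.94), at -0.052 without casein 7 and at -0.065 without casein 18. The Wnt list (17 tested) had a mean of 0.009, with Frzb at 0.37 and Ctnnb1 at 0.27, the Notch list (11 tested) of -0.007, with Maml1 at -0.26 and Numb at 0.19, and the EGF and FGF family list (7 tested) of -0.14, with Spry2 at -0.53. Without 1 array the EGF and FGF family mean ran from -0.19 to -0.073. The sign of the growth hormone list turned under quantile normalization and median centring, and that of the Wnt list under median centring.

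Metabolic and stress lists other than lipid synthesis did not pass either. Fatty acid oxidation and PPAR alpha target genes (19 tested, 6 positive and 13 negative) had a mean of -0.05, and 1 member, Cpt2, passed when adjusted over the list alone, while Pdk4 was at 0.44. That list passed without soy 149, at -0.14. Oxidative phosphorylation genes (34 tested, 25 positive and 9 negative) had a mean of 0.04, with Uqcrc2 at -0.23 and Cox6c at 0.23, and passed at 0.10 to 0.12 without casein 6 or soy 147. Glycolysis genes (23 tested) had a mean of 0.01, with Pgd at -0.23 and Pck2 at -0.31, and turned in sign under quantile normalization and median centring. The mean of xenobiotic and antioxidant genes (20 tested) was 0.06, with Gpx1 at 0.22, Gpx3 at 0.36 and Cyp1b1 at 0.29. Immediate early and stress genes (22 tested) had a mean of -0.02, with Cebpb at -0.33 and Junb at 0.38, and clock genes (7 tested) of -0.12, with Cry2 at -0.20 and Bhlhe41 at -0.46. Mean, median and camera direction differed in sign for 7 lists, milk protein, growth hormone and IGF, Wnt, Notch, antigen presentation, immediate early and glycolysis. Csn2, Wap, Krt14, Esr1, Pgr, Wnt5a and Ucp1 lay below the filter, at mean log2 signals of 7.03, 4.93, 7.17, 4.66, 6.1, 6.89 and 6.54, and no probe set is named for Adipoq or Wnt10b here.

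**Figure D3:**
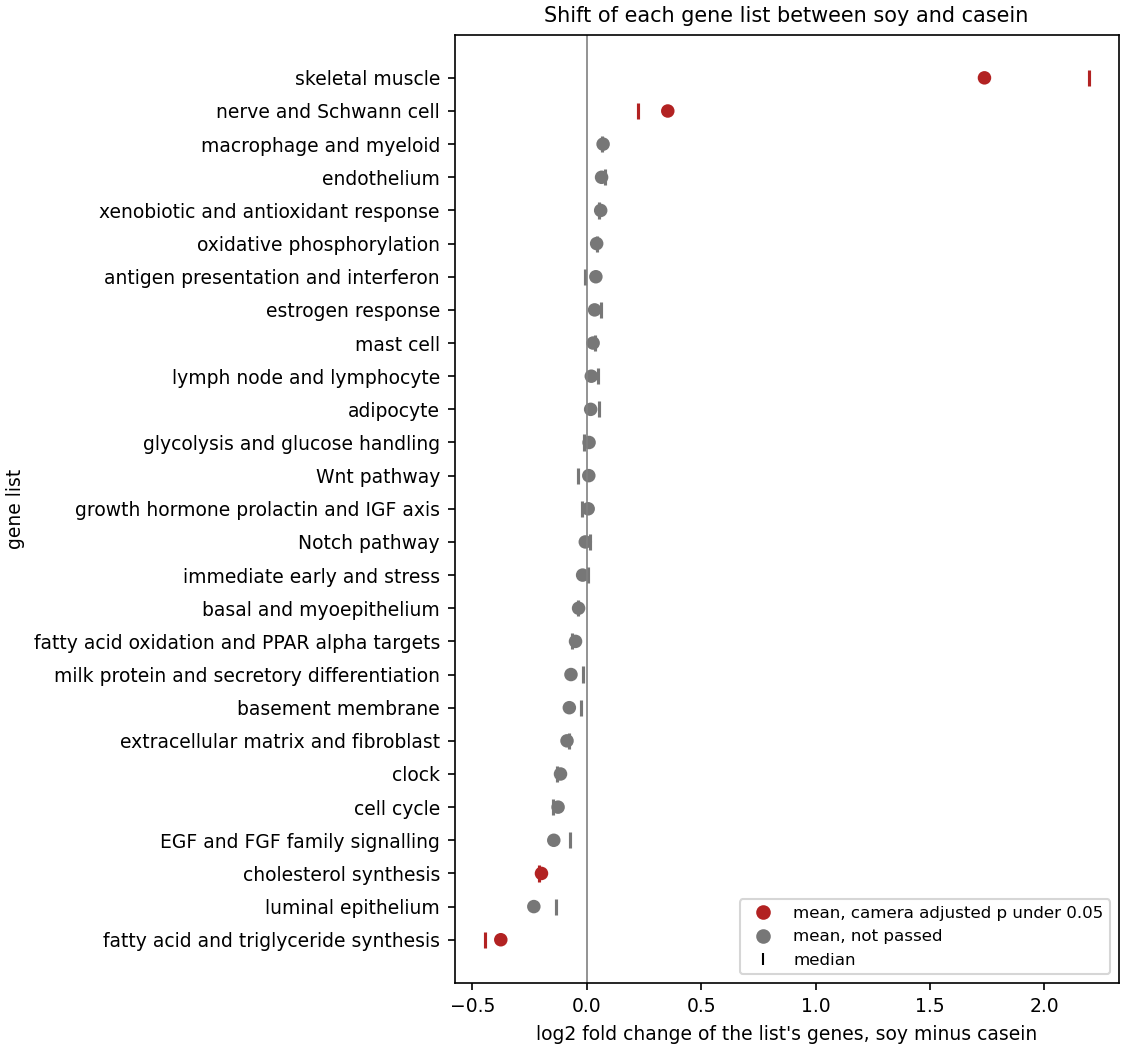
Mean (points) and median (ticks) log2 fold change, soy minus casein, of the tested genes in each gene list reported, with red for lists that passed in camera. Skeletal muscle stands at 1.74 and fatty acid and triglyceride synthesis at -0.38.

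RNA quality was compared by the 3' to 5' signal ratio of the control transcripts. The log2 ratio of beta-actin was 0.457 ± 0.14 (SD, n = 5) in casein and 0.568 ± 0.0649 (SD, n = 5) in soy, a difference of 0.11 with an exact permutation p = 0.151. For GAPDH it was 0.306 ± 0.176 (SD, n = 5) and 0.465 ± 0.13 (SD, n = 5), a difference of 0.159 with an exact permutation p = 0.175, and each had a Benjamini-Hochberg adjusted p of 0.175 in the exact test. Without casein 18 the GAPDH difference was 0.229 with an exact permutation p = 0.048.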

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

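The tests of lymph node signal, of adipocyte content, of muscle and lymph node signals as covariates, of the synthesis genes with arrays left out and of the splits by casein 6 and soy 149 were chosen after the result was seen.

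Of 250 sets of 5 values checked, each 1 measure in the arrays of 1 diet, 27 (10.8%) held an array apart. An array was apart when its gap to the nearest other array, over the whole range, exceeded 0.71, where chance gives about 5% for independent values. The sets come from the same arrays and are not independent, so 10.8% cannot be read as an excess. Many of the arrays apart were casein 6 and soy 149. In casein 6 the mean log2 signal was 8.727 for milk protein genes (10.81 to 11.55 in the other casein arrays), 10.25 for fatty acid oxidation genes (9.753 to 9.846), 7.324 for lymph node genes (9.896 to 10.25), 8.583 for antigen presentation genes (9.553 to 9.902) and 12.52 for skeletal muscle genes (7.11 to 8.205). In soy 149 it was 10.21 for fatty acid oxidation genes (9.663 to 9.802 in the other soy arrays), 8.194 for cell cycle genes (8.749 to 8.901), 10.09 for endothelial genes (9.735 to 9.761), 7.054 for lymph node genes (9.721 to 10.48) and 8.454 for antigen presentation genes (9.582 to 9.959). Lists with another array apart were Notch in soy 147, at 9.016 against 8.822 to 8.84, and the EGF and FGF family in casein 7, at 9.406 against 8.85 to 9.01.

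Single genes in casein 6 that stood apart were Gabarapl1 at 9.412 (9.708 to 9.763 in the other casein arrays), Cpt1b at 10.21 (7.875 to 8.466), Maml1 at 7.768 (8.381 to 8.596) and Myl1 at 13.62 (7.081 to 8.854). In soy 149 they were Fam107a at 8.508 (7.945 to 8.098 in the other soy arrays) and Col18a1 at 10.49 (9.941 to 10.08). In soy 147 they were Fasn at 11.33 (12.04 to 12.24), Cyp1b1 at 8.191 (8.757 to 8.908) and the cornified envelope and calmodulin-like genes Sprr1a at 12.91 (7.001 to 8.215) and Calml5 at 10.24 (7.372 to 7.894). The remaining genes were Med16 at 10.34 in soy 157 (10.05 to 10.13), Ctnnb1 at 12.59 in casein 20 (12.1 to 12.18), Tpsb2 at 8.906 in casein 18 (9.636 to 9.85) and Igf1 at 11.72 in casein 7 (12.29 to 12.37).

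Casein 6 had a mean Spearman correlation of 0.9361 with the other arrays, against 0.9619 to 0.9652 in the other casein arrays, and soy 149 and soy 157 had 0.9454 and 0.9507. The lowest lymph node mean of the other 8 arrays exceeded the higher of casein 6 and soy 149 by 2.4 on the log2 scale, which is consistent with little lymph node in those dissected glands. The lowest skeletal muscle mean of casein 6, soy 149 and soy 157 exceeded that of every other array by 0.868, short of the 1 required beforehand. The rule counted soy 147 among the other arrays, but it also carried muscle signal, at 11.23, so the rule cannot decide on muscle. Soy 147 had a mean correlation of 0.9554 as well, against 0.9625 in soy 155 and 0.963 in soy 159. The arrays with the highest muscle signal were thus those that correlated least with the others. Whether dissection brought the muscle signal was not tested. The lymph node list shares Cd74 with the antigen presentation list and Glycam1 with the milk protein list, and Myl1, an abundant muscle gene, was at 13.62 in casein 6. The biological difference between the diets was not tested as a source of these arrays, which lie in both diets.

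Fatty acid and triglyceride synthesis genes were lower in soy by a mean of -0.376. Fewer adipocytes were assumed to lower adipocyte genes as much, which was not tested. The adipocyte mean differed by 0.0167 (95% interval -0.431 to 0.464), an interval that holds the synthesis shift. Within arrays the synthesis mean minus the adipocyte mean differed by -0.393 (95% interval -0.676 to -0.109; exact permutation p = 0.0079, the smallest the assignments can give). Under that assumption this argues against fewer adipocytes as the whole source. The synthesis list was followed up for its shift in these same data, so this p is not an independent test. With muscle and lymph node signals as covariates the shift was -0.217 (95% interval -0.68 to 0.246), which holds 0 and the uncorrected value alike, against -0.779 to 0.0271 before. The shift was -0.507 (95% interval -0.973 to -0.0416, exact permutation p = 0.0286, the smallest those 8 arrays can give) without casein 6 and soy 149, and -0.36 (95% interval -1.05 to 0.327, exact permutation p = 0.2) without the 4 arrays with the highest muscle signal, where camera in limma still called the list (adjusted p = 0.0019). The estimate stayed negative in both settings, but the interval of the second holds 0. The first dropped casein 6, at 10.69 below the casein mean of 10.91, and soy 149, at 10.84 the highest soy array. Leaving out these 2 arrays therefore widens the difference by itself. Over the genes tested with all arrays, the muscle mean still differed by 2.28 without casein 6 and soy 149. With all arrays it differed by 1.74, so that setting cannot decide on muscle. The 4 casein and 2 soy arrays of the other setting leave too wide an interval to exclude muscle in the dissected gland, and diet stays open as well.

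Chance could not be excluded for the counts of lists and of probe sets with an unadjusted p under 0.05. There were 100 splits of the 10 arrays, the real one included, drawn from 126. Of these, 45 had at least the 433 such probe sets of the diets (highest other 1286). With casein 6 and soy 149 on the same side, 38 of 47 splits reached 433, with a median of 635 (166 to 1286). Of the 52 other splits that part these arrays, as the diets do, 6 reached it, with a median of 251 (124 to 750). The count of the diets thus ranked higher among splits that part these arrays than among all 100. The real split called 0 probe sets, so that all 100 reach that count by construction and it decides nothing (highest other 3). The 4 lists called were reached or exceeded in 86 of 100 splits, and the highest other split called 16, which points to a structure of the samples. The 47 splits with casein 6 and soy 149 on the same side called a median of 11 lists (6 to 16), and the 52 others that part them, as the diets do, a median of 5.5 (0 to 12), of which 38 called at least 4. With an estimated correlation 0 lists were called in any split. The synthesis list was called in 50 of the 100 splits.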

How the results depend on the processing

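The settings that leave out several arrays, use muscle and lymph node signals as covariates or permute list means were chosen after the result was seen. No paired analysis was possible because the diets share no replicate numbers. The number of arrays limits the precision, and no signal over background was measured. In 23 alternatives 0 probe sets passed in limma (272 to 843 with an unadjusted p under 0.05, smallest adjusted p 0.0839), and 45 passed the rule of unadjusted p and 1.5-fold. The 4 lists became 0 with an estimated correlation, 0 with fry, 0 with the exact permutation of array means, 9 without the 4 arrays with the highest muscle signal, and 3 to 8 without 1 array (7 without casein 10 and 8 without soy 149). The synthesis list passed in 22 of 26 alternatives (-0.53 to -0.22) and in 10 of 10 that left out 1 array (-0.45 to -0.26). It did not pass at -0.38 with an estimated correlation (adjusted p = 0.97), with fry (0.98) or in the exact permutation (adjusted p = 0.96), nor at -0.22 with covariates (adjusted p = 0.071). Cholesterol synthesis passed in 21 of 26, skeletal muscle in 19 of 25 and nerve in 18 of 25. The actin covariate moved them to -0.32, 2.71 and 0.53, and the covariates give no value for the muscle and lymph node lists themselves. The GAPDH ratio difference ran from 0.115 to 0.229 without 1 array (exact permutation p = 0.048 without casein 18), and the actin difference from 0.0688 to 0.153. Lists that passed only under another setting were, besides those named for single arrays, matrix (-0.15) and cell cycle (-0.13) with quantile normalization, cell cycle with no filter (-0.12), the actin covariate (-0.22) and tissue covariates (-0.16), and adipocyte (0.23) with tissue covariates. They were also oxidative phosphorylation (0.090) with array weights, macrophage (0.098) with the actin covariate, and basement membrane (-0.15), macrophage (0.14) and oxidative phosphorylation (0.089) without casein 6 and soy 149. Without the 4 arrays with the highest muscle signal they were luminal (-1.15), basal (-0.76), basement membrane (-0.15), macrophage (0.26), lymph node (0.16), mast cell (0.28) and oxidative phosphorylation (0.13). That setting left 2 soy arrays, soy 155 and soy 159, and soy 159 was low in both epithelial lists. Of 94 gene fold changes 84, and of 28 lists 11, kept their direction in all alternatives. For those that turned, none of which passed in the main test, the cause was not tested. Of the 94 gene values 41, and of the 28 list means 27, moved by over 1.5 times or turned in sign when 1 array was left out, with ranges of -0.70 to -0.34 for Acat2, -0.36 to -0.039 for Acta2, 0.077 to 0.25 for Alas2, -0.67 to -0.27 for Bhlhe41, 0.14 to 0.36 for Cfd and -0.52 to -0.16 for Cidea. They were 0.12 to 0.29 for Cnp, -0.59 to -0.24 for Col4a5, 0.15 to 0.36 for Cxcr5, 0.10 to 0.41 for Cyp1b1, -0.53 to -0.26 for Cyp51, -0.60 to -0.26 for Egfr, 0.089 to 0.26 for Fabp4 and 0.23 to 0.44 for Frzb. Further ranges were 0.23 to 0.47 for Gpx3, -0.31 to -0.050 for Hdc, -0.34 to -0.14 for Igf1, 0.22 to 0.56 for Junb, 0.45 to 0.85 for Mal, -0.41 to -0.17 for Maml1 and 0.36 to 0.79 for Mbp. They were 0.13 to 0.27 for Numb, 0.29 to 0.53 for Pdk4, -0.29 to -0.00019 for Plin2, 0.13 to 0.35 for Pparg, 0.90 to 1.83 for RT1-Bb, -0.62 to -0.29 for Scd and 0.16 to 0.50 for Tpsb2. With quantile normalization the values were adipocyte -0.044, growth hormone and IGF axis -0.0093, glycolysis -0.015 and Fabp4 -0.046. With median centring they were adipocyte -0.0048, growth hormone and IGF axis -0.016, Wnt -0.013, lymph node -0.0020 and glycolysis -0.012. With no filter they were milk protein 0.10, growth hormone and IGF axis -0.029, Wnt -0.050, macrophage -0.0061, mast cell -0.0074 and immediate early 0.029. With the filter at the 60th percentile they were Wnt -0.052, Notch 0.040 and lymph node -0.030, with log2 of signal plus 16 Krt18 -0.029, and with the mean of a gene's probe sets estrogen response -0.0023. With array weights they were adipocyte -0.027, growth hormone and IGF axis -0.052, Wnt -0.060, lymph node -0.16, antigen presentation -0.046 and Krt18 -0.81. With the actin ratio as covariate they were basal 0.058, adipocyte -0.069, fatty acid oxidation 0.032, Wnt -0.014, Notch 0.048, lymph node -0.39, antigen presentation -0.054, oxidative phosphorylation -0.0054, glycolysis -0.039, Cpt1b 0.16 and Krt18 -0.026. Without casein 6 and soy 149 they were adipocyte -0.16, growth hormone and IGF axis -0.047, Wnt -0.012, glycolysis -0.0013, Xdh -0.013, Cpt1b 0.058 and Krt18 -0.68. Without the 4 arrays with the highest muscle signal they were estrogen response -0.071, growth hormone and IGF axis -0.064, Wnt -0.068, glycolysis -0.0038, Ctnnb1 -0.0069, Cd37 0.33, Hdc 0.10, Calml5 -0.11 and Krt18 -1.22. With muscle and lymph node covariates they were estrogen response -0.070, Wnt -0.017, glycolysis -0.015, Krt18 -0.0063 and Lep 0.049. Leaving out 1 array gave ranges of -0.79 to 0.14 for Cd37, -0.34 to 0.24 for Cpt1b, -0.98 to 0.63 for Krt18, -0.65 to 0.063 for Prlr and -0.076 to 0.20 for Xdh. For lists the ranges were -0.055 to 0.032 for Notch, -0.12 to 0.11 for Wnt, -0.11 to 0.15 for adipocyte, -0.18 to 0.30 for antigen presentation, -0.43 to 0.21 for basal and -0.22 to 0.0012 for cell cycle. They were -0.019 to 0.078 for estrogen response, -0.14 to 0.041 for fatty acid oxidation, -0.032 to 0.069 for glycolysis, -0.051 to 0.030 for growth hormone and IGF axis, -0.084 to 0.010 for immediate early and -0.66 to 0.068 for luminal epithelium. They were -0.53 to 0.64 for lymph node, -0.0028 to 0.18 for macrophage, -0.081 to 0.20 for mast cell, -0.55 to 0.18 for milk protein and -0.016 to 0.12 for oxidative phosphorylation. Among lists that kept their sign, they were 0.022 to 0.084 for endothelium, 0.027 to 0.088 for xenobiotic and antioxidant genes and -0.15 to -0.071 for clock.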

Other observations

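The test of SREBP1 and insulin induced genes was chosen after the result was seen.

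In casein 6 and soy 149, where lymph node and antigen presentation genes had their lowest means, macrophage and myeloid genes had means of 9.987 and 9.787, against 9.869 to 10.51 in the other 8 arrays, and mast cell genes had means of 9.647 and 9.475, against 8.71 to 9.575. No test across arrays was run on these means. Luminal epithelial genes ranged from 7.329 in casein 6 and 7.37 in soy 159 to 9.926 in casein 7, a wider range than adipocyte genes, which ran from 10.89 to 11.93.

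Glucocorticoid exposure, a fasted state and lower SREBP1 and insulin driven transcription were weighed as hypotheses for the lower synthesis genes. The mean of 18 glucocorticoid induced genes differed by 0.0687 (95% interval -0.259 to 0.397; exact permutation p = 0.746, adjusted p = 0.746), with Fkbp5, an inhibitor of the glucocorticoid receptor, at 0.583 and Cebpb at -0.329. For 21 fasting and FOXO induced genes it was 0.0714 (95% interval -0.0882 to 0.231; exact permutation p = 0.357, adjusted p = 0.536), with Pdk4 at 0.443 and Gadd45a at -0.363. These intervals hold both 0 and 0.2, so neither may be excluded. The mean of 19 SREBP1 and insulin induced genes was -0.412 (exact permutation p = 0.0317, adjusted p = 0.0952, 18 of 19 negative), but 16 of the 19 are also in the fixed lists, so this test repeats the pattern and decides nothing, and Srebf1 itself was at 0.127. Fkbp5, Cebpb, Pdk4, Gadd45a and Srebf1 were named after their values were seen.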
